A study of Mus musculus with 6 samples.

How the data were processed

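The series holds 6 arrays of mouse A316 cells, a Cebpa-knockout adenocarcinoma line, 3 from cells given PTC-209 in 0.5% DMSO and 3 from cells given 0.5% DMSO. Per the labels' protocols, total RNA was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays. The free-text description of the samples speaks of embryo stages, which does not match their titles, source or treatment, and it was not used. Groups and replicate numbers were taken from the titles.

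The deposited table holds the authors' log2 expression values for 34760 probe sets on each array. The values were made with RMA (background correction, quantile normalization and summary of the probes of a set), per the submitters' processing notes, whose software version is not given in the sources used here. The log2 scale was read from the values, whose array medians lay between 4.07 and 4.14 and whose array means lay between 4.67 and 4.69. RMA gives every array nearly the same distribution, so a shift shared by most genes would not be seen. No genome build is given in the sources used here, and no coordinates are printed.

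A block of 6568 probe sets was left out before the fit, as the array's control probes. It was recognised by its run of identifiers, of which 99.8% follow each other by 1 against 0.3% among the other probe sets, and by 0 listed genes. Of the 28192 probe sets tested, 21640 have 1 gene symbol in the platform annotation, 1321 have several and 5231 have none listed. A probe set with several genes names none. The Entrez identifiers of 21553 of them were found in the RefSeq gene table, and 0 symbols needed an update. This gave 19937 named genes, each represented by its probe set with the highest mean over the 6 arrays. For 954 genes with more than 1 probe set, the others were examined where the gene is named. Dim probe sets were kept.

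Differences were tested on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit with treatment as the only term, eBayes with a constant prior). The p-values were adjusted by Benjamini and Hochberg over all 28192 probe sets, and a gene rose or fell when its adjusted p was under 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 5.27, with a median residual SD of 0.138. The correlation of arrays, across probe sets, which are not independent replicates, was 0.992 to 0.996 within a group and 0.97 to 0.974 between groups. The first principal component held 74.6% of the variance and the second 10.3%. Figures were drawn with matplotlib 3.10.9.

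The groups, tests, naming rule, gene lists and alternatives were fixed before the data were examined. The 34 gene lists were written from general knowledge and cover Polycomb complexes, Hox genes, the cell cycle, stress responses, metabolism, inflammation, signalling, lung epithelium and other cell types. They hold 995 entries, of which 917 matched a probe set, and 892 of their 967 distinct genes were measured. Some genes stand in more than 1 list. Each list was tested with limma's camera against all other genes, with a preset correlation of 0.01 between genes, adjusted over the 34 lists. With the correlation estimated from the arrays, 0 of the 14 calls held. That form of camera has only the 4 residual degrees of freedom of the arrays, while the preset form takes them from the number of genes. A call lost under it therefore need not mean that the genes of a list are correlated. Members were counted by direction, adjusted over all probe sets and over the list alone.

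The naming rule took Bmi1, Cebpa and the PRC1 members past the threshold. It took the 12 largest rises and 12 largest falls among genes whose groups did not overlap and whose brighter group reached the median brightness of 4.33, skipping predicted genes. It took up to 4 members of every list that camera called or that had at least 3 members past the threshold. This gave 136 genes. Members that make up a count of 5 or fewer are named too.

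The alternatives were a trended and robust prior, leaving out dim probe sets, quantile normalization again, cyclic loess, median centring, array weights, the replicate number as a block, a minimum fold change of 1.2, the mean of all probe sets of a gene, leaving out each array in turn, an estimated correlation, and fry, a rotation test that asks whether a list's genes move on balance in 1 direction. Keeping the control block was added after seeing the data. The fit was tested on simulated data for this comparison, with 28192 probe sets and 50 genes changed at each size. It recovered 28% of the genes changed by 0.5 on the log2 scale, 90% at 1, 98% at 2 and 100% at 3, and called 7 unchanged probe sets. Few genes were changed in that simulation, so its adjusted threshold was stricter than in the real fit and these shares do not carry over to it. Camera recovered 2 of 2 lists shifted by 0.5 and called 0 of the 32 others. Genes were simulated independently of each other, and only those 2 lists changed. In the real data the estimated correlation reached 0.29, for lysosomes and autophagy. The 0 false calls therefore do not carry over to the real lists.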

Results

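Gene expression was measured on 6 Affymetrix arrays of A316 cells, a mouse adenocarcinoma line in which Cebpa, the gene of the transcription factor C/EBP alpha, is knocked out. On 3 arrays the cells had been given PTC-209, a small molecule that the labels describe as a Bmi inhibitor, in 0.5% DMSO, and on the other 3 they had been given 0.5% DMSO alone. The comparison asks which transcripts differ when Bmi1, a subunit of the Polycomb repressive complex PRC1, is targeted in a line without C/EBP alpha, in a study of lung adenocarcinoma. The dose and the exposure time are not given in the sources used here. A total of 28192 probe sets were tested, and they gave a value to 19937 named genes. The median log2 value of an array over all 34760 deposited probe sets, control block included, lay between 4.07 and 4.14. The precision is limited by the number of arrays, 3 per group. The labels do not say whether the arrays of a group came from separate cultures, so the p-values of single genes measure only the spread between these samples, which may be technical. The camera p-values with a preset correlation compare a list with other genes and rest on the spread across genes, not between arrays. Group values below are mean log2 expression ± SD of 3 arrays. Where the dimmer group lies under the median brightness of 4.33, the 2 levels stand in place of a fold, since a level near the background leaves the fold and its rank uncertain.

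In cells given PTC-209, most members of the lists of mitosis (47 of 47), DNA replication (40 of 43) and cholesterol synthesis (14 of 21) fell, and most of the ATF4 stress response (39 of 41) and of lysosomes and autophagy (25 of 34) rose. By limma's camera with a preset correlation between genes, 8 of 34 lists were lower and 6 higher, and 0 of these 14 calls held with an estimated correlation (smallest adjusted p = 0.0628). Slc7a11, which imports cystine, rose 23.1-fold, from 6.33 ± 0.21 to 10.85 ± 0.07 (adjusted p = 8.60e-08). Cxcl5, a chemokine that attracts neutrophils, fell the most, from 10.40 ± 0.16 to 5.44 ± 0.03, a 31.2-fold lower level (adjusted p = 5.31e-08). In the limma fit 2565 genes rose and 2741 fell, together 26.6% of the genes. Of these, 444 rose and 857 fell at least 2-fold, and 46 rose and 203 fell at least 4-fold. The arrays of the groups did not overlap for 8066 genes, or 40.5%, where chance gives 10%. Counted over probe sets, 3340 rose and 3333 fell. When the test required a fold change above 1.2, the counts were 1270 genes higher and 1610 lower. Among the genes the naming rule took, that requirement ended the calls of Bmi1, Cbx8, Pcgf1, Pcgf3, Ring1, Scmh1, Yaf2, Mtf2, Cdkn1b, Cdkn2b, Cebpb, Bcl2l11, Tiparp, Nfe2l2, Fabp5, Ly6g, Rps3, Rps7 and Rpl6.

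The 12 largest rises included, besides Slc7a11, Car6, a secreted carbonic anhydrase (from 3.36 to 7.87), and Napb, a factor of membrane fusion (from 3.56 to 7.62). Gadd45a, a growth arrest and DNA damage gene, was 10.7-fold higher, and Hmox1, haem oxygenase, was 9.67-fold higher. Chac1, which degrades glutathione, was 9.46-fold higher and the lipoprotein receptor Vldlr 9.21-fold higher. Crebrf (8.39-fold), the pseudokinase Trib3 (8.28-fold) and the mitochondrial arginase Arg2 (from 4.12 to 7.14) followed. Lilr4b, from 2.87 to 7.30, and Lilrb4a, from 3.74 to 7.14, encode leukocyte immunoglobulin-like receptors. They are near-identical neighbours, which adds to the uncertainty of how much each rose. Among the largest falls, the calcium-binding protein S100a4 was 26.9-fold lower, the monocyte chemokine Ccl2 was 20.3-fold lower, and the epithelial mucin Muc1 went from 7.87 to 3.55. Plac8 (16.4-fold), Igfbp7 (15.3-fold), the claudin Cldn2 (from 7.07 to 3.20) and the matrix protein Efemp1 (from 7.58 to 3.74) were also lower. The mitotic kinesin Kif15 was 13.1-fold lower and troponin T, Tnnt2, 12.1-fold lower, and ceruloplasmin, Cp, went from 7.88 to 4.20. Trgv1, a T cell receptor gamma segment, fell from 6.61 to 2.57. For all 24 genes the limma adjusted p lay between 5.31e-08 and 2.58e-06. All 3 arrays of 1 group lay above all 3 of the other, as the naming rule requires. Members named further on because they make up a count of 5 or fewer were chosen after their values were seen, unless the naming rule takes them too.

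**Figure D1:**
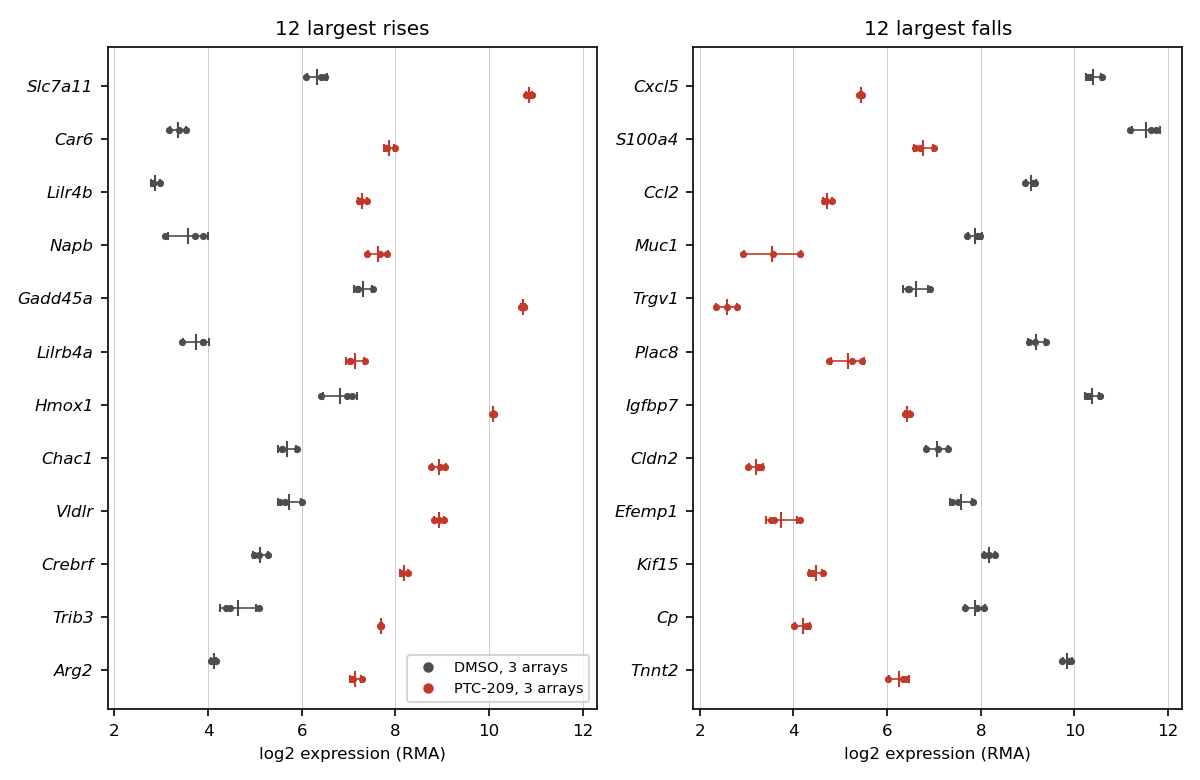
Log2 expression (RMA, x axis) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) on each of 3 DMSO arrays (grey) and 3 PTC-209 arrays (red), with a tick at the group mean and a bar for 1 SD. The groups are separate for every gene shown, as the naming rule requires, from Slc7a11 (6.33 against 10.85) to Tnnt2 (9.85 against 6.25).

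Bmi1 mRNA fell with PTC-209, from 7.55 ± 0.14 to 7.01 ± 0.075, and was lower on all 3 treated arrays than on any DMSO array. The level was 1.45-fold lower (95% confidence interval 1.23 to 1.71, log2 difference -0.54, SE 0.105, adjusted p = 0.00424). The array reads the mRNA and not the protein. Of the 18 measured PRC1 components 7 rose, 10 did not pass the threshold and 1, Bmi1, fell (7 rises and 1 fall adjusted over the list alone). Cbx8, a chromodomain subunit, rose by 0.69 on the log2 scale and Phc2 by 0.55. Pcgf1 rose by 0.45, Scmh1 by 0.43, Pcgf3 by 0.38, Ring1 by 0.37 and Yaf2 by 0.37. As a set the list was not called (limma camera, adjusted p = 0.1). Camera called it after quantile normalization was applied again (adjusted p = 0.0266; 0.0266 to 0.311 over the alternatives with camera), and fry, which tests a list against no change and not against other genes, called it too (adjusted p = 0.00224). The Bmi1 call ended when the test required a fold change above 1.2 (adjusted p = 0.0942; 0.00165 to 0.0942 over the alternatives). Cbx8, Phc2 and Bmi1 passed whichever of the 6 arrays was left out, but the count of rises fell to 3 without DMSO replicate 3 or PTC-209 replicate 1, to 4 without DMSO replicate 1 and to 5 without any other array, and Scmh1 also failed after median centring.

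**Figure D2:**
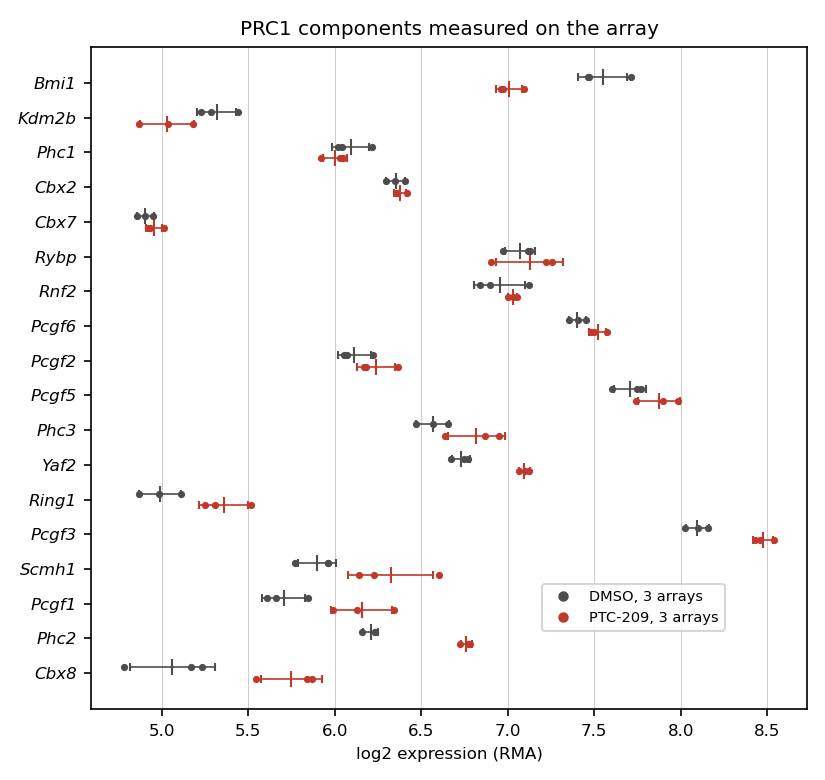
Log2 expression (RMA, x axis) of the 18 measured PRC1 components on each of 3 DMSO arrays (grey) and 3 PTC-209 arrays (red), with a tick at the group mean and a bar for 1 SD. Bmi1 lies at 7.55 in DMSO and 7.01 with PTC-209, while Cbx8 moves from 5.06 to 5.75 and Phc2 from 6.21 to 6.76.

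Among PRC2 components, Ezh1, a histone H3 methyltransferase, rose 2.52-fold, from 5.64 ± 0.08 to 6.97 ± 0.09 (adjusted p = 9.98e-06). Of 11 measured members 2 rose, Ezh1 and Phf1, and 3 fell, Phf19 (from 4.84 to 4.14), Rbbp7 (1.62-fold) and Mtf2 (1.38-fold); adjusted over the list alone the counts were 3 and 3 (camera adjusted p = 0.613). The Hox genes, classical Polycomb targets, were not called as a set: 2 of 36 rose and 0 fell (1 and 0 adjusted over the list alone), with a median log2 difference of 0.046 and an adjusted p of 0.356. Those past the threshold were Hoxc8 (0.48 on the log2 scale) and Hoxa13 (0.33), both dim. The list count of rises was 1 for PRC2 without DMSO replicate 3 or any 1 PTC-209 array, and 1 for Hox genes without DMSO replicate 2 or 3 or PTC-209 replicate 2 or 3.

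Cebpa itself was below the median brightness of all probe sets in both groups and its difference did not pass the test, at 3.65 ± 0.16 in DMSO and 3.79 ± 0.12 with PTC-209 (log2 difference 0.14, SE 0.114, adjusted p = 0.473). Whether the probe set lies in the deleted part is not given in the sources used here, so this level does not check the knockout. Of the 6 measured C/EBP family members 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.119). Ddit3, the stress factor CHOP, rose 4.75-fold, Cebpg 1.61-fold and Cebpb 1.59-fold, while Cebpd fell from 4.78 to 3.97. The ATF4 list also holds Ddit3, Cebpg and Cebpb.

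The lists of cell division were lower by camera, with an adjusted p of 7.17e-47 for mitosis and 7.25e-32 for replication. With an estimated correlation the adjusted p was 0.0628 for mitosis and 0.106 for replication, neither past the threshold. All 47 measured G2/M and mitosis genes were lower with PTC-209 and 0 higher (47 and 0 adjusted over the list alone), with a median log2 difference of -2.14 and falls between 1.05 and 3.30. Cyclin B2, Ccnb2, went from 9.68 ± 0.09 to 6.38 ± 0.22, a 9.87-fold lower level. The kinetochore gene Nuf2 was 7.53-fold lower, the checkpoint kinase Bub1b 6.88-fold lower and the kinesin Kif20b 6.82-fold lower. Of 43 DNA replication and S phase genes 40 fell and 0 rose (41 and 0 adjusted over the list alone), with a median of -1.62. The ribonucleotide reductase subunit Rrm2 was 9.41-fold lower, and the checkpoint kinase Chek1 8.41-fold, while the primase subunit Prim2 went from 7.36 to 4.17 and Dscc1, of the clamp loader, from 6.42 to 3.50.

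Replication-dependent histone genes, which are transcribed in S phase, were lower as a set (camera adjusted p = 0.00197; adjusted p = 0.14 with an estimated correlation). Of 14 measured 8 fell and 2 rose (9 and 2 adjusted over the list alone): H4c4 was 4.22-fold lower, H2bc3 went from 5.55 to 3.88 and H2ac4 from 5.12 to 3.12, and H2bc4 was 2.62-fold and H1f2 1.41-fold higher. These genes share long near-identical stretches, so the level of each copy is uncertain. The call was lost when dim probe sets were left out (adjusted p = 0.0947; 0.000878 to 0.14 over the alternatives with camera). Among 7 CDK inhibitors 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.337). Cdkn1a, also on that list, matched no probe set. Cdkn2b, p15, was 1.44-fold higher, while Cdkn3, a CDK phosphatase, was 6.33-fold lower and Cdkn2c, p18, went from 6.42 to 5.74. Cdkn2a, the locus of p16 and p19ARF, was lower, at 5.32 ± 0.07 in DMSO and 4.94 ± 0.16 with PTC-209 (adjusted p = 0.0278), a call that was lost without DMSO replicate 1 or 3 or PTC-209 replicate 1 or 2, where 2 members fell. Cdkn1b, p27, was 1.36-fold higher by its brighter probe set (limma adjusted p = 0.0243). A second, dim probe set fell past the threshold (log2 difference -0.41, limma adjusted p = 0.0137). The direction of Cdkn1b is therefore open, although it counts among the 2 rises. The call of its brighter probe set was lost without DMSO replicate 3 or PTC-209 replicate 2 or 3, where 1 member rose.

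The integrated stress response, the program that the transcription factor ATF4 drives, was higher as a set (camera adjusted p = 4.07e-30; adjusted p = 0.125 with an estimated correlation). Of 41 measured members 39 rose and 0 fell (40 and 0 adjusted over the list alone), with a median log2 difference of 1.21. Besides Slc7a11, Chac1, Vldlr and Trib3, described above, the list's remaining members that passed lay between 0.35 and 2.93 on the log2 scale. The ER unfolded protein response was also higher (camera adjusted p = 1.01e-05; adjusted p = 0.14 with an estimated correlation). Of 28 members 12 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.29. The co-chaperone Dnajb9 was 3.14-fold higher, Selenos 2.16-fold, the chaperone Hyou1 2.13-fold and the transcription factor Xbp1 2.13-fold. The ER list's rises numbered 7 without DMSO replicate 3, 11 without DMSO replicate 1 and 8 without any other array.

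Genes of lysosomes and autophagy were higher: 25 of 34 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 0.59 and a camera adjusted p of 2.95e-12 (adjusted p = 0.208 with an estimated correlation). The autophagy receptor Sqstm1, p62, went from 8.36 ± 0.08 to 11.20 ± 0.04, a 7.16-fold higher level. The lysosomal enzyme Hexa was 3.33-fold higher, the proton pump subunit Atp6v0d1 2.52-fold and Fnip1, a partner of folliculin, 2.47-fold. Targets of NRF2, the oxidative stress factor, were higher as a set, with 16 rises and 5 falls among 31 (16 and 5 adjusted over the list alone; camera adjusted p = 0.00252; adjusted p = 0.311 with an estimated correlation). Hmox1 rose from 6.82 ± 0.36 to 10.09 ± 0.02, and thioredoxin reductase, Txnrd1, was 3.41-fold higher. The epoxide hydrolase Ephx1 was 3.29-fold lower, and Akr1c13, Gstm1, Ugdh and Akr1b8, also detoxifying enzymes, fell too.

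Genes of glycolysis and hypoxia were higher, with 14 rises and 1 fall, of Stc1, among 33 (15 and 2 adjusted over the list alone; camera adjusted p = 0.00245; adjusted p = 0.381 with an estimated correlation). Ndrg1 was 7.58-fold higher, the angiogenic factor Vegfa 3.85-fold, the glucose transporter Slc2a1 3.73-fold and the ER oxidase Ero1a 2.91-fold. Of 22 heat shock protein genes 7 rose and 2 fell (10 and 2 adjusted over the list alone). Bag3 was 1.63-fold, Hsph1 1.62-fold and Dnajb4 1.61-fold higher, while the small heat shock protein Cryab was 2.92-fold lower and Chordc1 1.39-fold lower. The heat shock list passed narrowly (camera adjusted p = 0.0456; adjusted p = 0.283 with an estimated correlation). It was not called without DMSO replicate 1 (adjusted p = 0.11), PTC-209 replicate 1 (0.0826) or PTC-209 replicate 2 (0.0629), nor under 5 other settings with the preset correlation (0.0179 to 0.283 over the alternatives with camera), and it had 1 fall when any array other than DMSO replicate 1 was left out.

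Cholesterol synthesis was lower: 14 of 21 genes fell and 1 rose (15 and 2 adjusted over the list alone), with a median of -0.74 (camera adjusted p = 4.65e-08; adjusted p = 0.172 with an estimated correlation). The sterol reductase Tm7sf2 was 4.37-fold lower, the sterol isomerase Ebp 3.02-fold, the isopentenyl isomerase Idi1 2.94-fold and Fads2, a fatty acid desaturase, 2.78-fold. The gene that rose was Srebf2, the transcription factor of the pathway (0.43 on the log2 scale). The list had 2 rises without DMSO replicate 1 and 0 without DMSO replicate 2 or 3 or PTC-209 replicate 1 or 2. Of 22 genes of fatty acid and lipid synthesis 7 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.194). The elongase Elovl6 was 3.06-fold lower, Acss2 2.50-fold, acetyl-CoA carboxylase, Acaca, 2.38-fold, fatty acid synthase, Fasn, went from 7.74 to 6.74, and Dgat2, Lpin1 and Elovl5 rose. Subunits of oxidative phosphorylation were lower, 14 of 36 falling and 2, Sdhd and Ndufb3, rising (15 and 3 adjusted over the list alone; median -0.15, camera adjusted p = 0.00197; adjusted p = 0.311 with an estimated correlation). Cyc1 was 2.23-fold, Uqcrb 2.11-fold, Ndufa9 1.87-fold and Ndufv2 1.86-fold lower. Its rises numbered 1 without DMSO replicate 2 or PTC-209 replicate 1 or 3, and 0 without DMSO replicate 3 or PTC-209 replicate 2.

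Inflammatory genes under NF-kB were lower as a set, though not all in the same direction: 15 of 33 fell and 6 rose (17 and 8 adjusted over the list alone; median -0.37; camera adjusted p = 0.000168; adjusted p = 0.14 with an estimated correlation). The falls were led by chemokines and cytokines, with Ccl20 from 6.89 to 3.30 and Il33 from 6.24 to 3.53 besides Cxcl5 and Ccl2. Of 33 interferon response genes 10 fell and 1, Ifi35, rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.00997; adjusted p = 0.14 with an estimated correlation). The median log2 difference of the interferon list was only -0.087, and 22 of its members did not pass the threshold. Herc6 went from 5.21 to 3.41 and Ifit2 from 5.56 to 3.92, while Ifitm3 was 2.27-fold and Irgm1 1.86-fold lower. Without DMSO replicate 1 the interferon list had 2 rises. Targets of TGF-beta and BMP were lower: 9 of 23 fell and 3, Inhba, Ski and Tgif1, rose (10 and 4 adjusted over the list alone; camera adjusted p = 0.00407; adjusted p = 0.14 with an estimated correlation). The median of the TGF-beta and BMP list was only -0.098 against a mean of -0.697, and 11 of its members did not pass the threshold. The BMP targets Id3 and Id2 were 7.51-fold and 6.53-fold lower, the connective tissue growth factor Ccn2 8.46-fold and the activin antagonist follistatin, Fst, 6.37-fold.

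**Figure D3:**
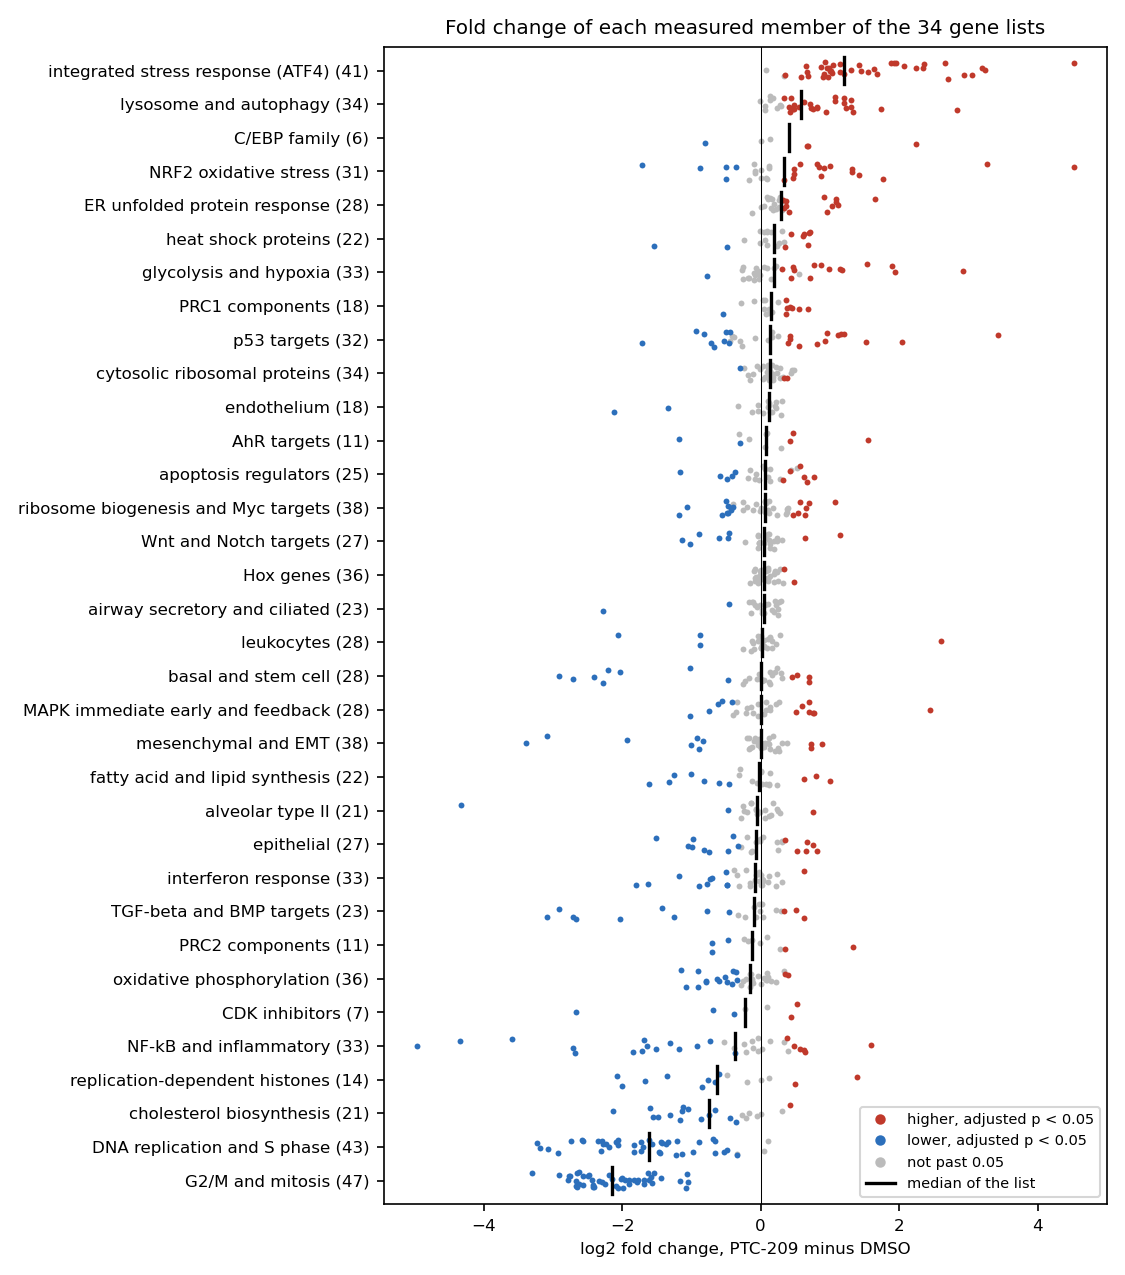
Log2 fold change, PTC-209 minus DMSO (x axis), of each measured member of the 34 gene lists (rows, number measured in brackets), 1 dot per gene: red higher and blue lower at an adjusted p under 0.05, grey not past it, with a black bar at the list's median. The medians run from 1.21 for the ATF4 list to -2.14 for the G2/M and mitosis list.

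Markers of epithelial and lung identity were not called as sets. Of 27 epithelial genes 6 rose and 9 fell (7 and 10 adjusted over the list alone; camera adjusted p = 0.396), with the keratins Krt7 (2.85-fold), Krt18 (2.06-fold) and Krt19 (1.99-fold) and the transcription factor Ehf (from 4.976 to 4.003) lower. Of 38 mesenchymal genes 3 rose, Zeb2, Snai2 and Itga5, and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.396). Sparc, a matrix protein, was 10.5-fold lower, the protease inhibitor Timp1 3.82-fold lower and the protease Mmp14 went from 7.71 to 6.71, besides the fall of Ccn2. Among 21 alveolar type II markers Etv5 rose and Muc1 and Fabp5 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.613), and a second Fabp5 probe set did not pass. Without DMSO replicate 3 that list had 2 rises. Among 23 airway secretory and ciliated markers 0 rose and 2 fell, Aldh1a1 (4.85-fold) and Ccdc39 (0 and 2 adjusted over the list alone; camera adjusted p = 0.981), with 1 rise without PTC-209 replicate 1. Of 28 basal and stem cell genes 4 rose, Hmga2, Myc, Cd24a and Klf4, and 8 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.163). Igf2bp1, an RNA-binding protein, was 5.30-fold lower, and a second, dim probe set of it did not pass.

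Markers of other cell types were mostly dim. Of 28 leukocyte genes 1 rose and 3 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.881). Cd68, a lysosomal glycoprotein of macrophages, went from 7.42 ± 0.04 to 10.03 ± 0.04, a 6.11-fold higher level, while the mannose receptor Mrc1 was 4.18-fold lower and Cd14 1.84-fold lower. Ly6g, dim in both groups, fell from 3.32 to 2.445, a call that was lost when any array other than DMSO replicate 1 was left out and under the trended prior. Without DMSO replicate 1 or PTC-209 replicate 1 the list had 2 rises. Of 18 endothelial genes 0 rose and 2 fell, Cdh5 from 9.49 ± 0.05 to 8.15 ± 0.21 and Flt1 from 7.63 ± 0.18 to 5.51 ± 0.19 (0 and 2 adjusted over the list alone; camera adjusted p = 0.976), and 1 rose without DMSO replicate 2.

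Targets of p53 went both ways among the measured members, which leave out Cdkn1a and Bax, as neither matched a probe set. Of 32 measured 13 rose and 9 fell (13 and 11 adjusted over the list alone; camera adjusted p = 0.396). Beside Gadd45a, the noncoding RNA Pvt1 was 4.10-fold and Trp53inp1 2.86-fold higher, while Ephx1 fell; a second Pvt1 probe set near the floor did not pass. Of 25 apoptosis regulators 6 rose and 5 fell, Bcl2, Casp6, Casp8, Bad and Cflar (9 and 5 adjusted over the list alone; camera adjusted p = 0.603). The anti-apoptotic Bcl2 was 2.24-fold lower, and Casp2 (1.71-fold), Casp9 (1.59-fold) and the pro-apoptotic Bcl2l11 (1.55-fold) were higher. The falls in that list numbered 3 without DMSO replicate 2 or 3 or PTC-209 replicate 1 or 2.

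Growth signalling was also mixed. Of 28 MAPK early and feedback genes 7 rose and 5 fell, Fos, Spry2, Spred1, Spry1 and Egr1 (7 and 6 adjusted over the list alone; camera adjusted p = 0.881), with the phosphatase Dusp4 5.45-fold and Spry4 1.71-fold higher and Fos 2.03-fold lower. Of 27 Wnt and Notch targets 2 rose, Jag1 and Dll1, and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.881), among them Hes1 (2.19-fold) and cyclin D1, Ccnd1 (2.02-fold). Of 11 targets of the aryl hydrocarbon receptor 3 rose, Slc7a5 (2.92-fold), Tiparp (1.38-fold) and Nfe2l2 (1.34-fold), and 2 fell, Aldh3a1 (from 5.19 to 4.02) and Cyp1a1 (4 and 2 adjusted over the list alone; camera adjusted p = 0.603), with 1 fall when any array other than DMSO replicate 1 was left out. Of 38 ribosome biogenesis and Myc target genes 7 rose and 10 fell (8 and 12 adjusted over the list alone; camera adjusted p = 0.976), with Nop14 2.11-fold and Myc 1.62-fold higher and Wdr12 2.27-fold and Polr1b 2.09-fold lower; the falls numbered 6 without PTC-209 replicate 2 or 3. Of 34 cytosolic ribosomal protein genes 2 rose, Rps3 and Rps7, and 1 fell, Rpl6, all by less than 0.4 on the log2 scale (0 and 0 adjusted over the list alone; camera adjusted p = 0.114). Rps7 and Rpl6 have further probe sets that do not all pass, none of the 3 calls held without DMSO replicate 3 or PTC-209 replicate 2, and camera called the set itself higher without DMSO replicate 2 (adjusted p = 0.0413), under the trended and robust prior (0.0186) and with the mean of all probe sets of a gene (0.00525; 0.00525 to 0.702 over the alternatives with camera), as did fry (0.0186). The rises of these ribosomal protein genes numbered 1 without PTC-209 replicate 1 or 3, and the fall was lost when any array other than DMSO replicate 1 was left out. Each of the 3 also lost its call under at least 1 of the rescalings: Rps3 under cyclic loess, Rps7 under cyclic loess and repeated quantile normalization, and Rpl6 under median centring. The median, mean and test differ in sign, or the median is 0, for the ribosome biogenesis, mesenchymal, airway, basal and stem cell, leukocyte, endothelial and Wnt and Notch lists.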

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

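The control block of 6568 probe sets, which no comparison of the report uses, carries a signal. When it was fitted together with the other probe sets, a test chosen after the data were seen, 437 of its probe sets were higher with PTC-209 and 261 were lower. That is 10.6% of the block, against 19.8% of the other probe sets in the same fit. At least 2-fold, 133 were higher and 75 were lower, and the median log2 difference of the block was 0.067. The annotation used here lists no gene for these probe sets, so none of them is named.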

How the results depend on the processing

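The direction of the Bmi1 difference and the counts of genes, probe sets and lists in each direction were recomputed under the alternatives that apply to each; keeping the control block, chosen after seeing the data, was run for the counts of genes and probe sets. A minimum fold change of 1.2 gave 1270 genes higher and 1610 lower, and 1559 probe sets higher and 1931 lower, since it asks for more than a difference from 0. Under it the Bmi1 difference stayed at -0.54 and its adjusted p was 0.0942. With an estimated correlation 0 lists were called higher and 0 lower, the smallest camera adjusted p being 0.0628. The TGF-beta and BMP list had an estimated correlation of 0.01, the same as the preset. Its camera adjusted p still went from 0.00407 to 0.14, so for that list a higher correlation did not end the call. With an estimated correlation camera takes its degrees of freedom from the arrays, 4 here. With the preset correlation it takes them from the number of genes. For that list the loss follows from this difference. With fry, which does not compare a list with other genes, 12 lists were higher and 14 lower. Under all other settings these counts stayed within 1.5 times those of the report. Leaving out 1 array at a time gave 2068 to 2647 genes higher and 2264 to 2484 lower, 2644 to 3378 probe sets higher and 2740 to 3064 lower, 5 to 7 lists higher and 8 lists lower. Over these 6 fits Bmi1 lay between -0.584 and -0.459, past the threshold in each, and Cebpa between 0.051 and 0.199, past it in none. Cebpa has no value where dim probe sets were left out. Keeping the control block gave 2155 genes higher and 2392 lower. The share of higher among called probe sets lay between 44.2% with cyclic loess and 52.4% without DMSO replicate 1. Of 2007 values for 134 other named genes, 1943 kept direction and side of the threshold, 64 in 18 genes lost the threshold, 0 reversed and 0 gained it. The labels do not say whether a shared replicate number pairs the samples. Residuals of arrays with the same number correlated at 0.23, 0.07 and 0.07, which with 3 arrays per group does not settle it. With the replicate block, 2689 genes were higher and 2844 lower, 3628 and 3482 probe sets, and 5 and 8 lists, and the adjusted p of Bmi1 was 0.00754. Array weights gave DMSO replicate 1 a weight of 0.47, against 0.84 to 1.51 for the others; the cause was not tested. With 3 arrays per group small changes can be missed, and dim genes near the background have compressed differences.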

Other observations

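The 4 lists of this paragraph, and the tests on ER stress, leukocytes and Hox genes, were chosen after the results were seen. Genes of the circadian clock were higher with PTC-209: 15 of 17 measured rose and 0 fell, with a median log2 difference of 0.75. The camera adjusted p was 8.88e-10, and 0.0259 with an estimated correlation, both adjusted over these 4 lists alone. The lists of the report were adjusted over 34, so the 0.0259 cannot be set against their values. The repressor Bhlhe41 went from 3.52 ± 0.35 to 6.43 ± 0.30, the nuclear receptor Nr1d1 from 8.12 ± 0.30 to 9.91 ± 0.09, Bhlhe40 from 7.69 ± 0.15 to 9.11 ± 0.07 and Per1 from 4.88 ± 0.17 to 6.18 ± 0.13 (SD, n = 3 arrays). Ciart was 6.46-fold higher. Genes of the Fanconi pathway and homologous recombination, which repair DNA crosslinks and breaks, were lower: 17 of 22 fell and 0 rose, with a median of -1.30 (camera adjusted p = 1.13e-13; adjusted p = 0.0521 with an estimated correlation). Fancb went from 5.95 to 3.70, and Brca2 was 4.29-fold and Rad54l 4.34-fold lower. Of 31 proteasome subunits 10 rose and 3 fell (camera adjusted p = 0.206), and of 16 mitochondrial aminoacyl-tRNA synthetases 2 rose and 4 fell (camera adjusted p = 0.298). As these lists were picked from the same data, their directions are not independent evidence.

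The fall of the mitosis and replication lists was weighed against 2 technical explanations. A trend with brightness would move bright genes of any kind, yet 0 of 10000 random lists of 90 genes matched on brightness had a median as low as the joint -1.975, and theirs ran from -0.251 to 0.303. An array that stands apart would carry the calls, yet every fit without 1 array kept at least 85 of the 87 called members, or 97.7%. Both explanations are argued against. A candidate explanation is slower proliferation or a smaller share of dividing cells under PTC-209, which expression values alone cannot separate; the dose and time stay open, and no cell count was analysed here.

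The rise of the ATF4 list was weighed in the same way. Of 10000 lists matched on brightness 0 had a median as high as 1.207, and theirs ran from -0.347 to 0.377, which argues against a brightness trend. ER stress as the only source could raise the ER list alike; its 28 members, none of them shared with the ATF4 list, lay lower by 0.915 in the median, but 12 of them rose, so ER stress as a part or as the only source with unequal strength stays open. Amino acid shortage, mitochondrial stress and an effect of the compound on another protein of this pathway are further hypotheses and were not tested.

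Cd68, Lilrb4a, Lilr4b and Havcr2, genes better known from leukocytes, rose together. Havcr2 went from 5.69 ± 0.18 to 8.12 ± 0.09. Leukocytes in the treated cultures would bring their other transcripts too. The median shift of the other 27 leukocyte markers was 0.012 (SD 0.472), 0 of them rose and 3 fell, Mrc1, Cd14 and Ly6g. Ptprc, the pan-leukocyte CD45, stood at 3.17 ± 0.20 in DMSO and 3.06 ± 0.13 with PTC-209. These values argue against leukocytes, although 23 of the 27 markers lie below the median brightness. Expression of these genes by the tumour cells themselves is a hypothesis that these arrays alone may not settle, and for the near-identical Lilr4b and Lilrb4a shared probes stay open.

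Release of Polycomb repression at Hox genes is a hypothesis that the target of the compound brings up. The Hox list had a median shift of 0.046 and 2 of 36 members past the threshold, but 32 of the 36 lie below the median brightness, where the array may miss a small rise. Whether repression was released cannot be told apart from no release here.

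Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. In each of the 6 counts, only 1 split, the real one, gave as many. The real split gave 2565 genes higher and 2741 lower, and the highest other split gave 0 and 0 in limma; over probe sets it was 3340 and 3333 against 0 and 0. For gene lists it was 6 higher and 8 lower, and the highest other split reached 5 in its larger direction. Every other split sets 2 arrays of a treatment against 1, so it keeps part of the treatment difference between its groups and the rest in its residual spread. Counts of 0 genes can follow from that design alone, and the lists called there are not calls on samples without a difference.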
